A study of Zea mays with 12 samples.

How the data were processed

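Maize B73 seedlings were grown for 3 days at 28 C, labelled with 25 µM EdU for 20 min and moved to 100 µM thymidine, per the labels' protocols. Nuclei of the terminal 1 mm of root tip were sorted by EdU signal and DNA content into G1, early S, mid S and late S. DNA with EdU was immunoprecipitated in the S-phase groups, and G1 DNA was sequenced without immunoprecipitation as the reference. Libraries were made from 0.5 ng of DNA with 11 PCR cycles and sequenced as 150 bp paired-end reads, per the labels. There were 3 biological replicates in each of 4 groups, or 12 libraries, and sample groups were taken from the labels.

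The submitters' processing notes name Trimmomatic 0.39, Bowtie2 2.5.1 and SAMtools 1.9. The segmentation tool, its thresholds, its handling of reads that map to many places and the genome build are not given in the sources used here. The 1 deposited file holds categorical timing classes and coordinates, in windows of 10 kb, with no signal, ratio or count. Whether and how the authors combined the replicates is read only from the file being a single segmentation without library columns. Depth per sample is therefore unknown, and no interval from counting can be given.

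The class of each base, share, segment length, boundary and gap was computed from the segmentation as deposited. The outer 20% at each end of a chromosome was compared with the middle 60%. Genes came from the RefSeq gene table of the assembly Zm-B73-REFERENCE-NAM-5.0, which has symbols, biotypes and positions without strand, exons or products. Since no build was named, the match of the 2 coordinate systems was tested on the data: the correlation of gene counts with ES peaked within 10 kb of no offset on all 10 chromosomes. In 20 Mb windows, 91 of 102 peaked within 20 kb of no offset, against 2.49% by chance. All genes lay inside the extents of the 10 chromosomes, each taken to end at its last segment. No gene coordinate is printed, and any local difference between builds would move the gene assignments. Each gene took the class at its midpoint.

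Differences over chromosomes were tested by exact two-sided sign-flip permutation over 1024 patterns, and lists by an exact two-sided rotation of the classes over the gene order. The background was 33146 classified protein-coding genes, or 45512 genes of all types for the RNA types and pseudogenes. Adjustment was by Benjamini-Hochberg over 50 list tests and over 11 sign-flip tests. Analyses ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

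The design, the classical gene symbols, the RNA types other than microRNA and the list themes were fixed before the data were examined. The microRNA genes were not named in that design and were added to the RNA types. The lists had been written for product names, which the gene table lacks, so 16 of the themes were matched to symbols and synonyms and 2 lists were added (transcription factors of the MYB, bHLH, bZIP, WRKY, NAC and ERF families, and aquaporins). This was done with the data at hand but before the class of any list member had been looked at. The name lists together held 1.30% of the 47019 annotated genes on the chromosomes, so they cover mainly genes that have been given names. A single gene with the synonym RPA, an acidic ribosomal protein, entered both the ribosomal and the replication lists, and the cyclin list holds cyclin-dependent kinase inhibitors. Named were all located classical genes except 1 that is not reported here, for each list its first ES and LS member by position and all LS members where these were 5 or fewer, and the 3 longest segments of each class. Other genes named in the lists as examples, the gene-rich LS segments, the gene-free ES segment, the rRNA gaps and the longest gap were chosen after their values were seen.

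The tests were run on simulated data. The rotation test called 3.40% of 500 random rotations of the MADS-box list of 32 genes. Each was ranked among those same rotations, so this rate was bounded by construction and checks only the code. The rotation test called 90.0% of 200 lists of 30 genes with 25% in ES and 82.5% of 200 with 80% in ES. These rates are for single lists of the stated sizes, without the adjustment applied to the reported lists. They do not show the error rate for unrelated or clustered lists. Nor do they show how often shorter lists would be called after adjustment. The sign-flip test called 4.75% of 2000 sets of 10 chromosomes with no difference.

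Alternatives were other outer parts, mixed classes joined or split, segment length, Fisher's exact test, clusters counted once, rotation within chromosome parts and leaving out each chromosome. GC content, tandem repeat arrays, exon number, gene 5 prime ends and the product-based lists (disease resistance, F-box, receptor-like kinase, transposon-derived and uncharacterized proteins) were not analysed here, as they need sequence, strand, exons or products.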

Results

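Replication timing was mapped in root tip cells of the maize inbred B73 by Repli-seq, in which newly made DNA is labelled, cells are sorted by S-phase stage and the labelled DNA of each stage is sequenced. Nuclei from the terminal 1 mm of roots of 3-day seedlings were sorted after a 20 min pulse of the thymidine analogue EdU into G1, early S, mid S and late S, with 3 biological replicates in each of the 4 groups and 12 libraries in all. The values available were 1 segmentation of the genome without library columns, in which each segment carries a class: ES, MS or LS, read here as early, mid and late S, or a mixed class for neighbouring stages, ESMS and MSLS. The file gave no value per library and no read counts, so the depth behind each segment is unknown and no error between replicates can be given. Errors below are SDs over the 10 chromosomes, which are parts of 1 genome and not replicate plants, and p-values measure only the spread between chromosomes or along the genome. Coordinates are those of the deposited file, whose genome build is not given in the sources used here.

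MS was the class with the most sequence and ES the next. Of 2095.27 Mb classified in 20613 segments, MS took 33.3%, ES 27.9%, LS 20.5%, MSLS 9.48% and ESMS 8.83%. Over the chromosomes the share of ES was 27.6% ± 3.69 (SD, n = 10), lowest on chromosome 4 at 20.7% and highest on chromosome 1 at 32.5%. The share of LS was 20.8% ± 3.84 (SD, n = 10), lowest on chromosome 1 at 14.5% and highest on chromosome 7 at 26.8%. MS varied less, at 33.2% ± 2.44 (SD, n = 10), from 30.3% on chromosome 6 to 37.1% on chromosome 8. The single-stage classes together held 81.7% of classified sequence and the mixed classes 18.3%. Classes that skip or span all stages were almost absent, with 6 segments of early and late S and 3 of all 3 stages, 180 kb together. These shares are descriptive and carry no test.

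ES and LS domains were long, and mixed segments were short. Median segment length was 120 kb for LS, 110 kb for ES, 90 kb for MS, 40 kb for MSLS and 20 kb for ESMS. The longest ES segment lay on chromosome 6 from 173770001 to 177750000 (3.98 Mb) and held 186 protein-coding genes. The next were on chromosome 2 from 2750001 to 6480000 (3.73 Mb, 184 genes, among them the leaf boundary regulator lg1, with the lipoxygenase gene lox6 as its first named gene) and on chromosome 5 from 2800001 to 6440000 (3.64 Mb, 180 genes, the first named being MIR390b). The longest LS segment spanned 240001 to 5390000 near the start of chromosome 6 (5.15 Mb) and held 2 protein-coding genes. LS segments of 4.09 Mb on chromosome 7 (63390001 to 67480000) and 3.74 Mb on chromosome 1 (131270001 to 135010000) held 6 and 7 genes. The longest MS segment was 1.05 Mb on chromosome 8 (65380001 to 66430000, 6 genes), followed by 950 kb on chromosome 9 (105950001 to 106900000, 14 genes) and 800 kb on chromosome 4 (69270001 to 70070000, 14 genes). No mixed segment exceeded the 380 kb ESMS segment of chromosome 1 (213620001 to 214000000). The next longest ESMS segments were 270 kb on chromosome 7 and 220 kb on chromosome 1, and the longest MSLS segments were 360 kb on chromosomes 3 and 6 and 330 kb on chromosome 9. Of the ES segments of at least 1 Mb, 55 of 56 lay in the outer 20% at either end of a chromosome, and 43 of the 51 LS segments of that size lay in the middle 60%.

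**Figure D1:**
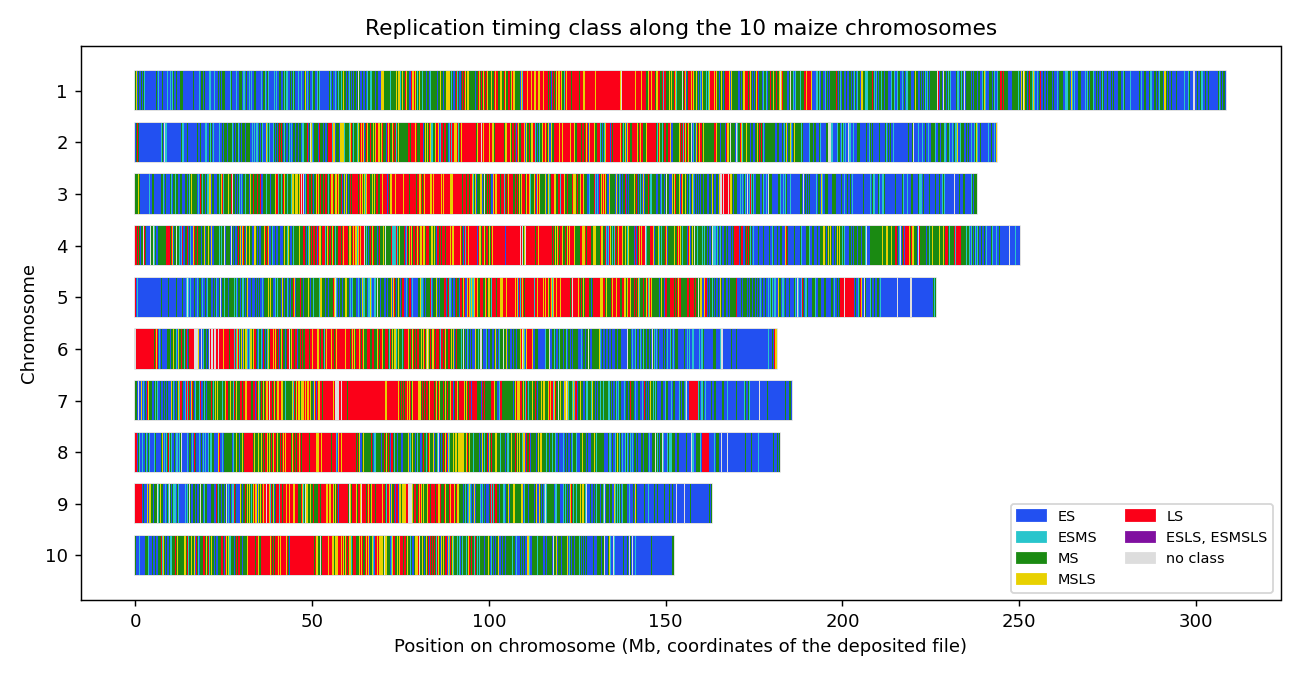
Timing class of each segment along the 10 chromosomes, drawn to scale against the position in Mb in the deposited file, with each colour standing for a class and grey for sequence without a class. Blocks of LS lie mainly in the chromosome interiors, where 43 of 51 LS segments of at least 1 Mb are found, and blocks of ES lie towards the ends.

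Neighbouring segments nearly always differed by a single step in the order ES, ESMS, MS, MSLS, LS. Of 19624 boundaries between touching segments of these 5 classes, 96.7% were single steps. In 100 shuffles of the segment order the mean was 50.4% and the highest value 51.3%. Since the mixed classes stand for neighbouring stages, single steps may follow in part from the class scheme, which the shuffles do not keep. A direct change between ES and MS occurred 604 times, between MS and LS 31 times and between ES and LS once. LS segments with touching neighbours on both sides were flanked by MSLS on both in 98.1% of 1654 cases, and ES segments by ESMS on both in 81.4% of 2571.

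Early replication was concentrated towards the chromosome ends and late replication in the interiors. ES took 48.1% ± 8.91 of classified sequence in the outer 20% at each end and 14.1% ± 3.56 in the middle 60%, a difference of 34.0 percentage points ± 10.3 (SD, n = 10), higher at the ends on 10 of 10 chromosomes. LS took 7.54% ± 6.39 of the ends and 29.6% ± 5.31 of the middle, and its difference of -22.1 points ± 8.77 was negative on 10 of 10. ESMS differed by 2.58 points ± 1.62, higher at the ends on 10 of 10, and MSLS by -8.73 points ± 2.31, lower on 10 of 10. MS differed by -5.81 points ± 7.80 and was lower at the ends on 9 of 10. Exact two-sided sign-flip tests over the 10 chromosomes gave p = 0.00195 for ES, ESMS, MSLS and LS, the smallest that 1024 sign patterns allow, and 0.0469 for MS; adjusted over the 11 such tests by Benjamini-Hochberg these were 0.00215 and 0.0469. When the whole class track was instead rotated along the joined chromosomes, which keeps its domains intact, the ES difference passed (exact rotation p = 0.0160) and the LS difference did not (p = 0.0539).

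The gradient was not symmetric. In the last 5% of the chromosome, in the direction of increasing coordinates, ES made up 77.7% ± 11.6 of classified windows, and in the first 5% it made up 52.9% ± 26.8 (SD, n = 10). LS peaked between 35% and 40% of the chromosome at 55.1% ± 28.4 and made up 0.585% ± 1.32 of the last 5%. No test was run on this asymmetry.

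**Figure D2:**
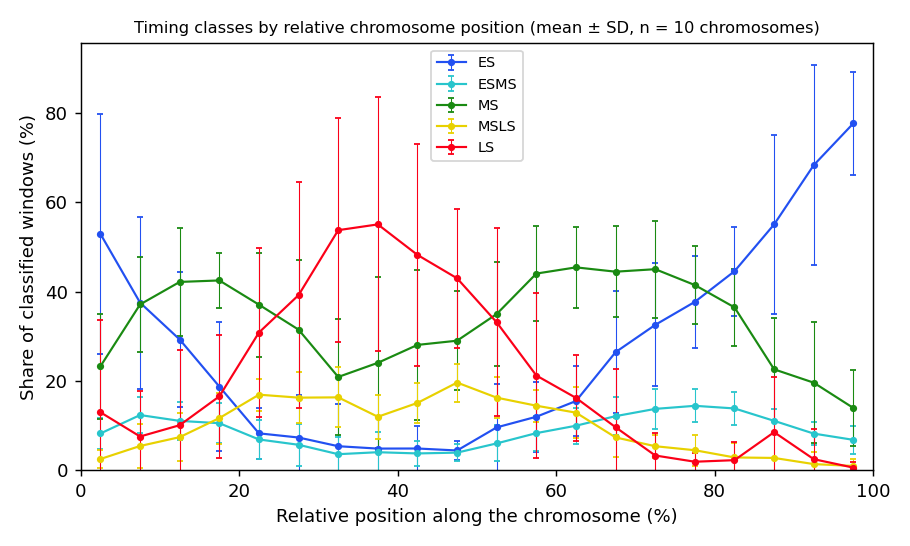
Share of classified windows (vertical axis, %) in each of the 5 classes against relative position along the chromosome (horizontal axis, %), in steps of 5%, with points at the mean and error bars of 1 SD over 10 chromosomes. ES falls from 52.9% at the start to 4.42% before the middle and rises to 77.7% at the end, while LS peaks at 55.1%.

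Gene content fell at every step from early to late. Protein-coding genes, assigned by their midpoint, stood at 31.3 per Mb ± 1.73 in ES, 21.1 ± 1.28 in ESMS, 11.6 ± 0.559 in MS, 6.99 ± 0.585 in MSLS and 3.69 ± 0.593 in LS (SD, n = 10). ES exceeded LS by 27.6 genes per Mb ± 1.77, or 8.48-fold, from 6.30-fold to 11.4-fold between chromosomes. ES held 18173 genes, 54.8% of the 33146 classified, against 1611, or 4.86%, in LS. Genes covered 16.0% ± 0.706 of ES sequence and 1.77% ± 0.193 of LS. Each neighbouring class differed from the next in the same direction on 10 of 10 chromosomes, as did ES against LS, with an exact sign-flip p of 0.00195 each and 0.00215 after adjustment over the 11 tests. The ES advantage held within chromosome parts, at 28.1 genes per Mb ± 5.41 in the outer parts and 22.7 ± 2.16 in the middle, and ES itself was denser in the outer parts, by 6.97 genes per Mb ± 3.56, on 10 of 10 chromosomes (exact sign-flip p = 0.00195, outside the family of 11).

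**Figure D3:**
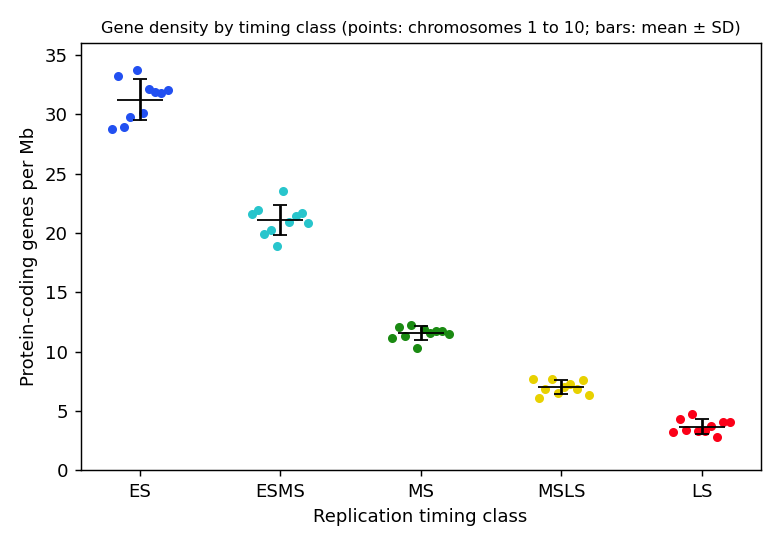
Protein-coding genes per Mb (vertical axis) in the 5 timing classes (horizontal axis), with a point for each of 10 chromosomes and bars at the mean ± SD. The classes fall in order from 31.3 in ES to 3.69 in LS, and the lowest chromosome of ES (28.8) lies above the highest of ESMS (23.6).

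Genes in ES were longer than those in LS. The median gene length per chromosome was 3340 bp ± 63.2 in ES and 1928 bp ± 253 in LS, a difference of 1413 bp ± 293, longer in ES on 10 of 10 chromosomes (SD, n = 10; exact sign-flip p = 0.00195). In the outer parts alone, where LS held 264 genes in all and between 5 and 110 per chromosome, the difference was 692 bp ± 2419 and was not distinguishable from 0 (exact sign-flip p = 0.426).

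LS was not empty of genes, and some ES segments held none. The LS segments with the most genes were on chromosome 4 from 217710001 to 218410000 (700 kb, 18 genes), chromosome 7 from 31580001 to 32630000 (1.05 Mb, 16 genes) and chromosome 4 from 30360001 to 30660000 (300 kb, 13 genes, or 43.3 per Mb). Among ES segments, 298 (9.37%) held no protein-coding gene, with a median length of 30 kb and a longest of 150 kb on chromosome 5 (49550001 to 49700000).

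Transfer RNA genes, long noncoding RNA genes and pseudogenes differed in class from all annotated genes. Of 864 classified tRNA genes 512 lay in ES, 59.3% against 51.0% of all classified genes. Rotation of the classes over the gene order gave a lower count (440.7 on average, exact rotation test, adjusted p = 0.00769). With ESMS added to ES the call was lost, at an adjusted p of 0.0513 by the same test. Protein-coding genes alone were at 54.8% in ES, nearer to the tRNA genes, and tRNA genes were not tested against them. In LS there were 33 tRNA genes against 60.8 by exact rotation (p = 0.0156, adjusted p = 0.0708), which did not pass; it passed with Fisher's exact test (adjusted p = 0.000387), with clusters counted once (0.00615) and with MSLS added to LS (0.0173), and not with rotation within chromosome parts (0.0814). Long noncoding RNA genes lay in ES less often, at 36.8% of 5205, and in LS more often, at 12.7% against 7.04% of all genes. Pseudogenes resembled them, with 39.4% of 4917 in ES and 13.1% in LS. Each of these differences had an exact rotation p of 2.20e-05, the smallest that the 45512 rotations can give, and an adjusted p of 0.000220. In the exact rotation test small nuclear RNA genes were at 61.8% in ES (adjusted p = 0.161), small nucleolar RNA genes at 54.7% (0.614) and microRNA genes at 50.9% (1), none passing. The small nuclear RNA genes passed with Fisher's exact test (adjusted p = 0.00445) and in none of the other 3 alternatives (0.0645 to 0.318). These tests were adjusted over 50, for 25 lists in ES and in LS.

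The ribosomal RNA genes stood apart. Of 884 annotated rRNA genes 672 lay in sequence without a class, against 535 of 33681 protein-coding genes. Of the 212 with a class, 173 were in LS, which the exact rotation test called (adjusted p = 0.000220). Those 173 all lay on chromosome 6, where a further 497 had no class. With members within 200 kb counted once, the 212 came to 7 clusters, 4 of them in LS. The call held on those few clusters by exact rotation (adjusted p = 0.0280). In ES there were 38 rRNA genes against 108.1 by exact rotation, which did not pass (adjusted p = 0.614); it passed with Fisher's exact test (1.69e-22) and with rotation within chromosome parts (0.0411), and not with clusters counted once (0.889) or with ESMS added (0.168). A single unclassified gap on chromosome 6 from 16700001 to 17400000 (700 kb) held 185 of these 497. On chromosome 2, 37 were in ES and 172 lay in the gap from 227620001 to 227680000 (60 kb). rRNA genes are repeated near-identical copies, and how reads that map to many places were handled is not given in the sources used here.

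Of 18 lists of protein-coding genes chosen by name, the zeins and the MADS-box factors departed from the genome in ES. Zeins, the seed storage proteins of maize, had 0 of 28 members in ES, against 15.4 by exact rotation (adjusted p = 0.000754), with 21 in MS, 6 in MSLS and gz27 in ESMS; the 19 zein pseudogenes also had none in ES. The 28 genes fall in 12 clusters. MADS-box factors, which include many regulators of flower development, had 8 of 32 in ES (25.0%, 17.5 by exact rotation, adjusted p = 0.00215), the first by position being MADS62, with zmm2, zmm16 and zmm31 among the others, and 17 in MS, among them zap1 and zag2. Their LS members were zmm6 (segment of 130 kb on chromosome 1) and MADS35 (60 kb, chromosome 8). The 584 genes on any list were at 53.9% in ES and 3.77% in LS, against 54.8% and 4.86% of all protein-coding genes; this was not tested.

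**Figure D4:**
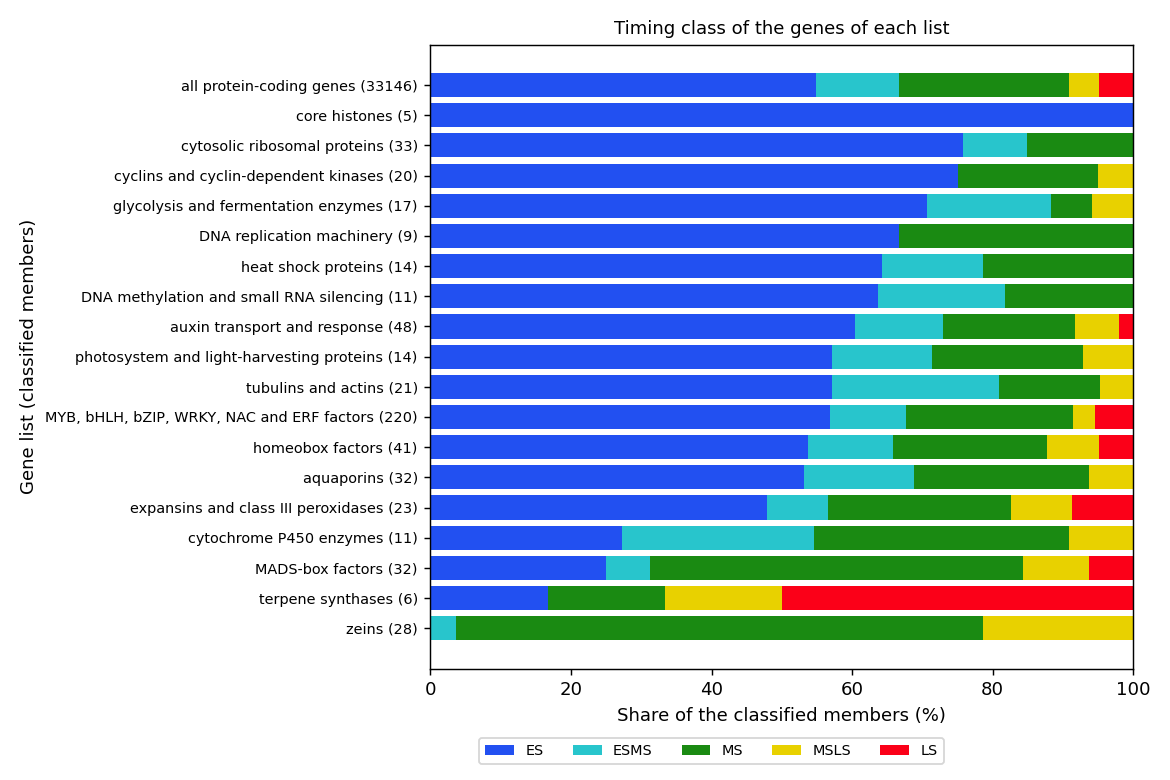
Share of classified members (horizontal axis, %) in each timing class, stacked by colour, for all protein-coding genes and the 18 lists, with the number of classified members in brackets. Zeins have no ES and 75.0% MS, MADS-box factors have 25.0% ES, and all protein-coding genes have 54.8% ES.

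The other 16 name lists did not pass in ES. Cytosolic ribosomal proteins had 25 of 33 in ES (18.1 by exact rotation, p = 0.0132, adjusted p = 0.0697), from rpl32 on chromosome 1 onwards, with the remaining 8 in ESMS or MS. By the same exact test core histones had 5 of 5 (p = 0.0577, adjusted p = 0.222), the first being H3C2. No higher count was possible for this list, so the test could not have called an excess. Cyclins, cyclin-dependent kinases and their inhibitors had 15 of 20 (exact rotation, adjusted p = 0.276), among them cdc2. DNA replication machinery had 6 of 9 (0.893), among them orc1, orc2, orc3, orc4 and PCNA, with MCM6 and MCM7 in MS. Glycolysis and fermentation enzymes had 12 of 17 (0.614), among them pdc3, heat shock proteins 9 of 14 (0.893), among them hsp18, DNA methylation and small RNA silencing genes 7 of 11 (0.961), among them dcl1, and auxin transport and response genes 29 of 48 (0.893), the first being AUX17, with ARF33 the only LS member. Photosystem and light-harvesting proteins had 8 of 14 in ES (first psbs1), tubulins and actins 12 of 21 (first tub1), homeobox factors 22 of 41 (first HB112) and aquaporins 17 of 32 (first tip1), each with an adjusted p of 1.

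In LS no name list passed adjustment, and at an unadjusted p under 0.05 only the terpene synthases did. They had 3 of 6 members in LS, tps11, tps23 and tps10, all on chromosome 10 (0.292 by exact rotation, p = 0.0139, adjusted p = 0.0697). They passed with Fisher's exact test, which treats neighbouring genes as independent (adjusted p = 0.00855), and in none of the other 3 alternatives (0.0554 to 0.127). tps1 was in ES, and tps26 and tps6 were in MS and MSLS. Expansins and class III peroxidases had 11 of 23 in ES (exact rotation, adjusted p = 0.893) with expB2 the first in ES and expB7 and EXPB1 in LS, and cytochrome P450 enzymes had 3 of 11 in ES (0.361), among them CYP727A4. The homeobox genes ocl4 and WOX3A were in LS. MYB, bHLH, bZIP, WRKY, NAC and ERF transcription factors had 125 of 220 in ES (exact rotation, adjusted p = 0.893) and 12 in LS (adjusted p = 0.946), the first by position being NAC78 and bZIP45. 12 of the 18 lists had no member in LS, where exact rotation gave only 0.243 to 1.60 members on average.

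Classical maize genes were found in all 5 classes. Of 56 symbols 47 were found, at 48 genes, of which 46 had a class and 25 (54.3%) lay in ES. ES held the alcohol dehydrogenase adh1, the sucrose synthases sh1 and sus1, the starch gene sh2 and the waxy starch synthase wx1. Also in ES were the anthocyanin genes c1, pl1, r1 and bz1, the leaf genes lg1 and lg2, ra3 and the DELLA genes d8 and d9. The same class held ts2, vp1, the benzoxazinoid genes bx1, bx2 and bx9, zfl1, rth3, phyB1, pdc1, tub1 and a gene matched to pep1. ESMS held y1, the anthocyanin gene a1, the homeobox gene kn1, ba1, gl8, the silencing gene mop1 and nrt2. MS held bt2, the zein regulator o2, tga1, ra2, id1, an1, bif2, the cell wall invertase gene incw1 and a different gene matched to pep1. The branching regulator tb1, mn1 and fie1 were in MSLS, and ra1 was in LS, in a segment of 190 kb on chromosome 7. p1 and the root gene rtcs had no class. The class changed at the lower coordinate of bt2 and r1 and at the higher coordinate of wx1, whose segment was 10 kb.

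Sequence without a class came to 36.54 Mb, 1.71% of the chromosomes, in 965 gaps of 20 kb at the median. Each chromosome was taken to end at its last segment, so any unclassified sequence beyond that is not counted. The longest gap was 910 kb on chromosome 9, from 77170001 to 78080000, with 22 protein-coding genes. The gaps held 535 protein-coding genes, or 14.6 per Mb, between the densities of MS and ESMS.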

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

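The alternatives with a minimum of 50 kb, the gene length by chromosome part, the gaps of more than 10 kb and the gene ends were chosen after the results were seen. Of 344 alternative values, 200 were list tests, most of which passed under neither setting. Leaving out a chromosome could not change the call for the ES and LS shares at the ends, gene density or gene length. All chromosomes had the same sign in these. The count of values that held is therefore not a measure of robustness. Of the 344, 318 kept direction and side of the threshold or stayed near the reported value. Another 10 changed sign, all in list tests past the threshold under neither setting. As members observed minus expected, these were snoRNA genes in ES at -7.39 with clusters counted once. With mixed classes joined they were zeins in LS at 3.46, cytochrome P450 enzymes in LS at 0.00142, MYB to ERF factors in LS at -0.972, aquaporins in ES at 0.687 and miRNA genes in ES at 0.300. With rotation within chromosome parts they were photosystem proteins in ES at -0.0428, homeobox factors at 0.0407 in ES and -0.108 in LS, and DNA methylation and silencing genes in ES at -0.0251; the cause was not tested. Splitting mixed classes equally gave ES 32.3%, MS 42.4% and LS 25.2%, and keeping only segments of at least 50 kb gave ESMS 4.88% and MSLS 7.24%, by construction. Rotating the class track left the LS difference at -22.5 points with p = 0.0539, the gene length difference in the outer parts was 692 bp (p = 0.426), and Fisher's exact test called 5 lists in LS against 3, with tRNA genes and terpene synthases gained, and 7 in ES against 5, with snRNA and rRNA genes gained; the cause was not tested. Rotation within chromosome parts called 6 lists in ES, with rRNA genes gained. Leaving out each chromosome gave 27.1 to 28.8% for ES, 8.47 to 9.03% for ESMS, 32.9 to 33.6% for MS, 9.16 to 9.83% for MSLS and 19.9 to 21.5% for LS. It gave 32.5 to 36.5 points for ES at the ends, -24.2 to -20.8 for LS, 27.3 to 27.8 genes per Mb and 1370 to 1477 bp. Limits of 5 kb on segments and 10 kb on gaps removed nothing and test nothing. No paired analysis was possible because the single file holds no value per replicate. GC content, repeat arrays, exon number, gene 5 prime ends and backgrounds or genes without uncharacterized products were planned and not run. Depth limits cannot be judged without counts.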

Other observations

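The 3 tests that match genes or windows on local gene number were chosen after the patterns they bear on had been seen, and the count of zein clusters was planned. No biological explanation was tested, since the design gives no contrast between groups for these patterns.

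ES took more of the chromosome ends than of the middle, and the ends are also richer in genes. If gene density within 100 kb alone were behind this, windows of 100 kb with equal numbers of genes would show little difference between ends and middle. They differed by 22.2 percentage points ± 8.35 (SD, n = 10), against 33.9 without matching, on 10 of 10 chromosomes (exact sign-flip p = 0.00195). In windows without a protein-coding gene ES took 14.8% ± 6.23 at the ends and 3.36% ± 1.05 in the middle. Gene number within 100 kb may account for part of the gradient but not for all of it. Gene density over longer distances was not matched. It stays open, as do gene expression, repeats and sequence composition.

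Few MADS-box genes lay in ES. Their neighbourhoods held a median of 7.5 protein-coding genes within 250 kb, against 11 for other genes, so low local density might produce the pattern. MADS-box genes were left out of the counts, so other genes counted themselves and MADS-box genes did not, also in the matching. Among 100000 random sets matched on that count, the share with 8 or fewer of 32 in ES was 0.00630 (one-sided), with a mean of 14.2 and 95% of sets between 10 and 19. Low density alone is unlikely to be the cause, and density together with chromosome part was not tested.

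No zein gene lay in ES. Counting each of 12 clusters once, exact rotation gave 6.58 in ES on average and p = 0.00118, which argues against tandem copies counted as many genes. Among sets matched on gene number within 250 kb outside the list, with 4.61 in ES on average, the share with none was 0.000740 (one-sided). This argues against density within 250 kb alone, if the clusters can be taken as independent. The matched genes were drawn independently, whereas clusters on the same chromosome may share timing, so the share may be too small. Other genes counted themselves and zeins did not, also in the matching. The sets were drawn from the whole genome, and chromosome and chromosome part were not matched. Of the 47 zein genes and pseudogenes, chromosome 4, where ES was lowest at 20.7%, held 24 in MS and 3 in MSLS. Chromosome 7, with ES at 24.6%, held 5 in MSLS, 4 in MS, 1 in ESMS and 1 in LS. Chromosome 1, where ES was highest at 32.5%, held 4 in MSLS and 1 in MS. The rest were on chromosomes 2, 6 and 9. Misplaced reads between near-identical copies could still blur classes within a cluster and were not tested.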
